A study of Homo sapiens with 15 samples.

How the data were processed

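Values in TPM per gene symbol were used as deposited; per the labels, the authors made the libraries from total RNA with a SMART-Seq v4 kit and used hg38. The file's name gives STAR gene TPM. The versions of the aligner and the annotation were not given in the sources used here. Each library's TPM summed to 1e+06. TPM gives no read counts and no absolute depth. Relative depth was read from the spacing of low values.

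Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Group, replicate and the comparisons Residual versus Primary, Relapsed versus Primary and Relapsed versus Residual were set from the labels before the data were examined, as were the gene lists and most of the other settings tried. XIST and Y-linked genes were left out of all fits. Of 19354 genes above 0 in any library, 7158 had a mean below 1 TPM and were left out, and 12196 were tested as log2(TPM + 1) with limma's trend option and no further scaling. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. The labels give 1 batch value for all libraries, so batch was not modelled. Replicate numbers were not used as a block in the main test.

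Of 37 fixed gene lists, 29 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists; of 928 list genes 908 were matched to the table. A list call is given beside its adjusted p with an estimated correlation, because members of a list vary together. Counts adjusted over the list alone used only the members' p-values.

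Genes were named by a fixed rule. It took SLC23A1 and KHSRP; the 8 largest rises and 8 largest falls per comparison among called genes whose groups did not overlap, with at least 5 TPM in the higher group; up to 3 members of each called list with the smallest adjusted p; and BCL2, MCL1, BCL2L1, BCL2A1, DNMT1, UCK2, TET2, IL3RA, CLEC4C, TCF4 and CD34. CD34 was below the filter and was not tested. Some genes that the rule names are not reported here. Other genes are named as chosen after their values were seen.

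In a self-test on simulated libraries, 82.1%, 92.5% and 80.6% of 67 genes shifted by 0.5 log2 were recovered in the 3 comparisons in the order above, and 100%, 100% and 95.5% at 1 log2. False calls numbered 8, 12 and 9 of 11996 unshifted genes. A simulated shift of the cholesterol biosynthesis list was found in each comparison, with 0 other lists called. Simulated genes varied independently, whereas that list had an estimated correlation of 0.398 in the data. The self-test therefore does not show how often genes or lists that vary together are falsely called.

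Other settings fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, removal of mitochondrial rRNA genes, a fit on only the 2 groups compared, sample weights, replicate number as a block, an estimated correlation for lists, and leaving out each library. Added after the data were seen were a minimum fold of 1.5, removal of rRNA, 7SL and ribosomal protein genes, and a correction for gene length and GC content on 11741 genes. That correction also centres each library, because it removes the library's mean deviation from the gene means. Unchanged groups were simulated 50 times to give the correlation that shared libraries produce. The genes IL3RA, CSF2RA, P2RY8, SLC25A6, CD99 and ASMTL, which lie in regions shared by X and Y, were listed at or near 0 and were not interpreted. Reads, splice forms and sequence variants were not analysed here.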

Results

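Gene expression was measured by RNA sequencing in 15 libraries of human leukaemia cells grown in mice as a patient-derived xenograft (PDX), a model in which a patient's cells are transplanted into immunodeficient animals. The labels name the cells as blastic plasmacytoid dendritic cell neoplasm (BPDCN), an acute leukaemia related to plasmacytoid dendritic cells, taken from bone marrow. Human cells were enriched from the mice before RNA was extracted, and the labels name no surface marker used for this. The libraries fell into 3 groups of 5: Primary, from mice given vehicle, and Residual and Relapsed, both from mice given venetoclax and azacitidine. Venetoclax is an inhibitor of BCL2, a protein that protects cells from apoptosis. Azacitidine is a cytidine analogue that depletes DNA methyltransferases. The series title concerns leukaemia that persists through therapy and names SLC23A1, a sodium-dependent vitamin C transporter, and KHSRP. The latter is a protein that binds AU-rich elements and promotes decay of the RNAs that carry them. The comparisons below ask how expression differed between the 3 disease states.

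The table gave TPM, a share of the library's transcripts, per gene symbol, and 12196 genes with a mean of at least 1 TPM were tested. Between 15806 and 17060 genes were above 0 in a library. TPM keeps no absolute depth. The spacing of low values gave the relative depth of the libraries, which spanned a factor of 5.24 between the shallowest and the deepest. The upper end rests on Relapsed replicate 5, for which 55 of 528 genes compared lay at the ratio used, the fewest of any library, and the next deepest was at 2.97. The mean ± SD of relative depth was 1.66 ± 0.726 in Primary, 1.87 ± 0.497 in Residual and 2.52 ± 1.68 in Relapsed (n = 5 each). Mitochondrial ribosomal RNA made up 2.60 ± 0.367% of TPM in Primary, 3.13 ± 0.333% in Residual and 2.75 ± 0.120% in Relapsed. Cytosolic ribosomal protein genes made up 29.6 ± 2.15%, 28.0 ± 0.838% and 27.7 ± 1.74%. The 15 libraries separated by disease state: Pearson's r across genes was 0.991 to 0.997 within a group and 0.967 to 0.988 between groups.

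**Figure D1:**
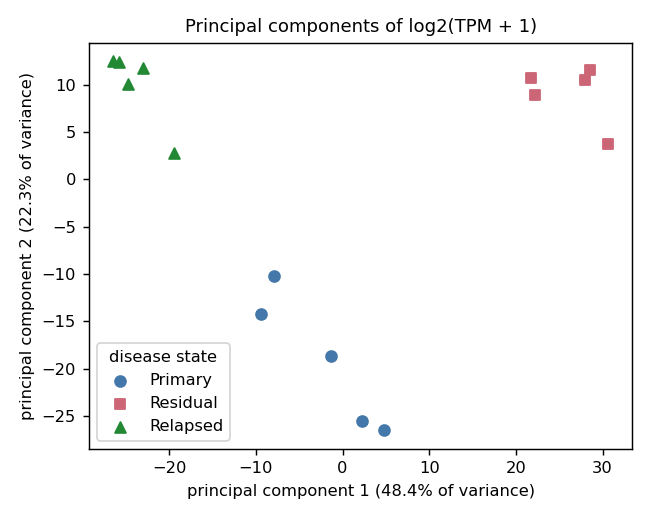
Scores of the 15 libraries on the first principal components of log2(TPM + 1), with the percent of variance in the axis labels; each symbol is 1 library and colour and shape give the disease state. The first component held 48.4% of the variance and had the Residual libraries at one end, Relapsed at the other and Primary between them, without overlap. The second, with 22.3%, set the 5 Primary libraries apart.

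In Residual cells the transporter SLC23A1 was expressed at less than the level seen in Primary cells. Its level was 6.78 ± 1.32 TPM in Primary, 3.22 ± 0.423 TPM in Residual and 8.10 ± 1.41 TPM in Relapsed (SD, n = 5 each). It fell by 0.87 on the log2 scale in Residual (SE 0.13, limma adjusted p = 3.36e-05) and was 1.10 log2 higher in Relapsed than in Residual (adjusted p = 1.02e-06). Each of the 5 Residual libraries (2.76 to 3.80 TPM) lay below each Primary library (4.78 to 8.29 TPM) and each Relapsed library (6.24 to 9.70 TPM). Relapsed and Primary differed by 0.23 log2 (adjusted p = 0.142). KHSRP was measured at 162 ± 18.5, 163 ± 4.42 and 169 ± 11.3 TPM and passed the test in no comparison (adjusted p = 0.872, 0.42 and 0.548). In hg38, SLC23A1 lies on chromosome 5 at 139367196 to 139385676 and KHSRP on chromosome 19 at 6413102 to 6424811. Both are annotated as protein-coding genes. The direction of KHSRP depended on the scaling between libraries. It turned to -0.14 log2 in Relapsed versus Residual under median-ratio scaling (adjusted p = 0.0302). After a correction for gene length and GC content, which also centres the libraries, it was -0.13 in both Relapsed comparisons (adjusted p = 0.0189 against Primary and 0.0150 against Residual). As tested but relative to the median of all genes, KHSRP was already at -0.10 against Primary and -0.12 against Residual. The SLC23A1 fall in Residual versus Primary was 1.83-fold on the scale of TPM + 1. A limma test against a minimum fold of 1.5 did not show that it exceeded that fold (adjusted p = 0.57).

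**Figure D2:**
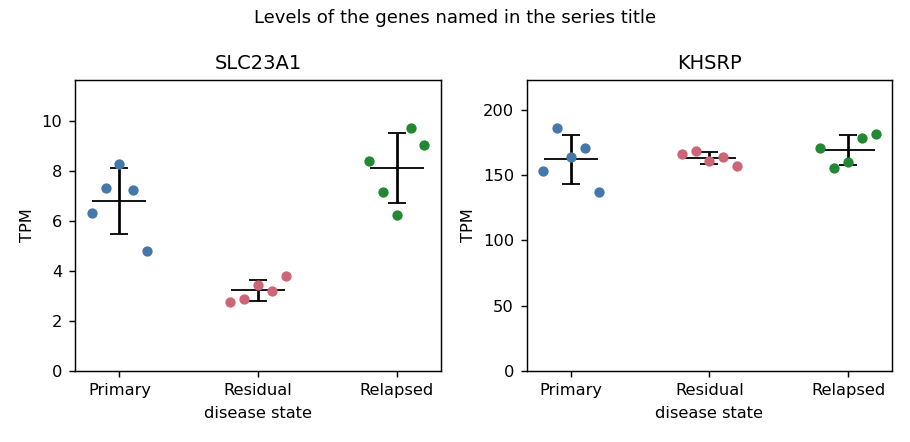
TPM of SLC23A1 and KHSRP in each library by disease state, on linear axes that start at 0; points are libraries, wide bars are means and error bars are SD (n = 5). SLC23A1 lay between 2.76 and 3.80 TPM in Residual and at 4.78 TPM or above in every other library, and the 3 groups of KHSRP values overlapped.

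The 8 largest rises in Residual cells, compared with Primary cells, included genes near 0 in Primary and genes already expressed there. The secreted disulfide isomerase AGR2 went from 0.408 to 93.7 ± 21.9 TPM, and GNLY, which encodes the cytolytic protein granulysin, from 15.4 ± 4.42 to 527 ± 132 TPM. The interferon-induced antiviral gene IFITM1 went from 43.0 ± 4.94 to 702 ± 149 TPM, a 15.7-fold rise on the scale of TPM + 1 (adjusted p = 4.11e-14). CD52, a small surface glycoprotein of lymphocytes, reached 53.2 ± 13.5 TPM from 0.954, and IL2RB, a receptor subunit for interleukin 2 and interleukin 15, reached 21.2 ± 4.29 TPM from 0.0776. LYZ (lysozyme) and MB (myoglobin) were also among the 8 largest rises, with log2 differences of 4.24 and 3.45. On the other side, the 8 largest falls included the sterol-regulated gene SQLE, squalene epoxidase (20.6 ± 3.60 to 5.47 ± 1.23 TPM). They also included 4 histone genes, HIST1H2BB, HIST1H2AE, HIST1H2BJ and HIST1H2AI, which fell by 1.94, 1.66, 1.55 and 1.49 log2. Histone genes of 1 family are near-identical, so reads can be shared among them. The receptor kinase EPHA2 (5.08 ± 1.45 to 0.590 ± 0.270 TPM) and PTCRA, the pre-T-cell receptor alpha chain (52.5 ± 3.32 to 18.2 ± 5.07 TPM), were also among them.

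**Figure D3:**
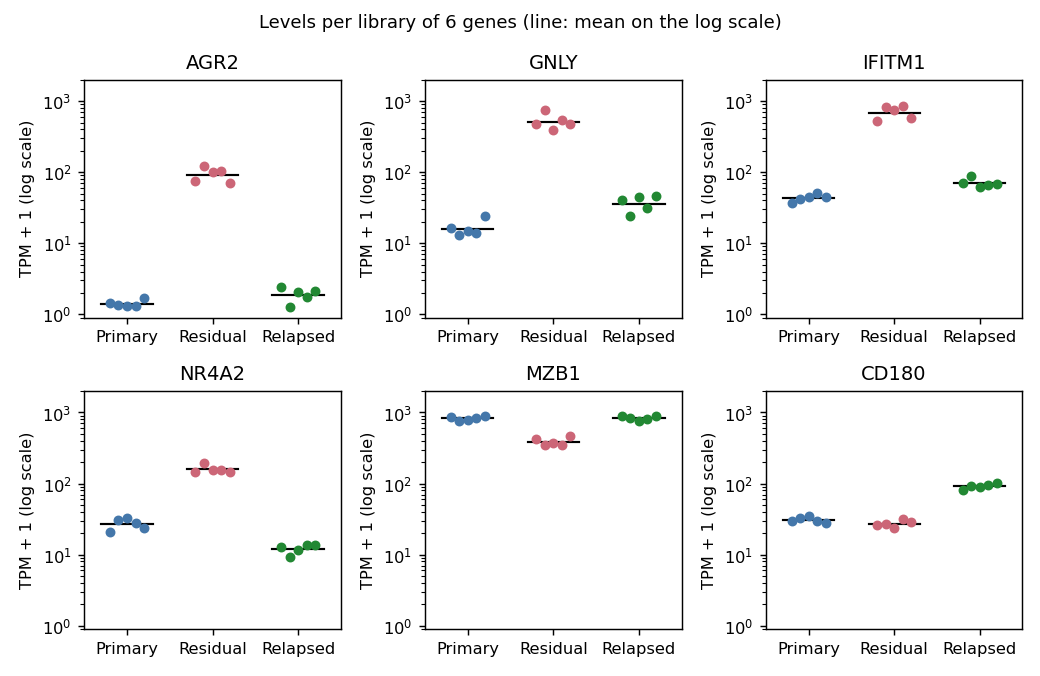
TPM + 1 on a log axis for 6 named genes in each library; points are libraries, colour gives the disease state and the black line is the mean on the log scale (n = 5). AGR2, GNLY, IFITM1 and NR4A2 were highest in Residual, MZB1 was lowest in Residual (390 TPM on average, against 829 in Primary and 843 in Relapsed), and CD180 was highest in Relapsed.

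The gene lists fixed beforehand grouped these changes. Of 28 measured markers of plasmacytoid dendritic cells and BPDCN, 21 fell, 2 rose and 5 did not pass in Residual versus Primary (2 rose and 22 fell when adjusted over the list alone). Among them MZB1, a chaperone of antibody-secreting and plasmacytoid cells, fell from 829 ± 55.9 to 390 ± 53.8 TPM, LILRA4, a plasmacytoid dendritic cell receptor, from 74.5 ± 5.38 to 33.4 ± 5.19 TPM, and TCL1A, a kinase co-activator, from 1127 ± 22.2 to 755 ± 39.4 TPM. The list as a whole was lower by camera (adjusted p = 1.43e-08), and this call was lost with an adjusted p = 0.224 with an estimated correlation. Cholesterol biosynthesis genes moved together: 20 of 24 fell and none rose (also 20 and 0 adjusted over the list alone), with FDFT1, squalene synthase, at 85.9 ± 6.50 against 48.7 ± 4.14 TPM. Cholesterol biosynthesis had adjusted p = 1.78e-09, and adjusted p = 0.224 with an estimated correlation. Of the G1/S genes of the cell cycle, 29 of 40 fell and none rose (31 adjusted over the list alone), among them PRIM1, the DNA primase, the transcription factor E2F8 and UHRF1, which guides maintenance of DNA methylation. Of the G2/M genes, 18 of 50 fell and none rose (21 adjusted over the list alone), among them HJURP, HMGB2 and AURKB. The list tests gave adjusted p = 7.72e-10 and 6.28e-05, and adjusted p = 0.39 and 0.717 with an estimated correlation.

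Of 21 measured targets of ATF4, the transcription factor of the integrated stress response, 9 fell and 2 rose in Residual cells by both adjustments, that is over all genes and adjusted over the list alone. The ATF4 list had adjusted p = 0.00539, and adjusted p = 0.39 with an estimated correlation. DDIT3, a pro-apoptotic factor of that response, fell from 93.8 ± 14.4 to 33.9 ± 1.58 TPM and ATF4 itself from 709 ± 18.9 to 518 ± 13.5 TPM. Genes of fatty acid oxidation were higher, with 9 of 18 risen and 1 fallen by both adjustments. Fatty acid oxidation had adjusted p = 0.00874, and adjusted p = 0.315 with an estimated correlation. CPT1A, which commits fatty acids to mitochondrial import, rose from 43.8 ± 5.57 to 109 ± 11.9 TPM, and SLC25A20, the carnitine carrier of the inner membrane, from 28.3 ± 0.967 to 53.2 ± 2.49 TPM. Of 76 measured cytosolic ribosomal protein genes 7 fell, 1 rose and 68 did not pass, with a median of -0.07 log2 (4 fallen and none risen adjusted over the list alone). The call of this list as lower (adjusted p = 0.00983) was lost under median-ratio scaling, with adjusted p = 0.165, and at adjusted p = 0.745 with an estimated correlation.

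Lists of antigen presentation, NF-kB targets and interferon-stimulated genes were called higher in Residual cells with the preset correlation, and none of these 4 calls held with an estimated correlation. Of 13 measured MHC class II genes 11 rose and none fell (12 adjusted over the list alone), among them HLA-DQA1 (141 ± 4.06 to 243 ± 14.7 TPM) and HLA-DRB1 (93.1 ± 1.25 to 135 ± 3.64 TPM), which share sequence with paralogs. Of the 14 MHC class I antigen presentation genes 10 rose and 1 fell by both adjustments, including HLA-B and the peptide transporter TAP1. The class II list had adjusted p = 8.11e-10 and the class I list adjusted p = 4.24e-05, with adjusted p = 0.103 and 0.058 with an estimated correlation. NF-kB targets had 9 of 16 risen and 1 fallen (10 and 1 adjusted over the list alone), with the feedback inhibitor TNFAIP3 at 22.7 ± 2.83 against 77.4 ± 12.8 TPM, NFKB1 at 16.8 ± 2.06 against 35.5 ± 3.98 TPM and BCL2A1, an anti-apoptotic BCL2 relative, at 0.884 ± 0.587 against 3.54 ± 0.791 TPM. The NF-kB list had adjusted p = 0.00109, and adjusted p = 0.155 with an estimated correlation. Of the interferon-stimulated genes 15 of 29 rose and 8 fell by both adjustments. The interferon-stimulated list had adjusted p = 0.0498, with adjusted p = 0.427 with an estimated correlation and 0.103 under median-ratio scaling. IFITM2 and IFITM3, relatives of IFITM1 that are near-identical to each other, rose 2.44-fold and 3.69-fold on the same scale.

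Lists fixed beforehand as markers of other cells and of handling moved with these groups. Their movement does not by itself show that such cells were present. Immediate-early genes, which respond within minutes to stimuli that include tissue dissociation, had 12 of 18 risen and 2 fallen in Residual (13 and 2 adjusted over the list alone), with NR4A2 at 26.0 ± 4.86 against 158 ± 21.3 TPM, FOS at 170 ± 19.6 against 446 ± 36.9 TPM and FOSB at 167 ± 27.9 against 544 ± 35.5 TPM. Immediate-early genes had adjusted p = 1.54e-07, and adjusted p = 0.23 with an estimated correlation. JUN and ATF3, named after their values were seen, were the members that fell. The T and NK cell marker list had 7 of 9 members risen and 1 fallen by both adjustments (adjusted p = 2.14e-07), and was the only list of the 14 called in this comparison that kept its call, with adjusted p = 0.0134 with an estimated correlation. Besides GNLY its members NKG7, a granule protein, and CD247, the zeta chain of the T-cell receptor, rose from 1.88 ± 0.669 to 15.1 ± 2.40 TPM and from 0.177 to 9.77 ± 1.18 TPM. B and plasma cell markers went the other way, with 7 of 10 fallen and 2 risen by both adjustments, including CD79A (30.1 ± 6.56 to 12.1 ± 0.626 TPM), the tyrosine kinase BLK and the B-lineage factor PAX5. The B and plasma cell list had adjusted p = 0.00271, and adjusted p = 0.297 with an estimated correlation. Of the monocyte markers LYZ rose, while CD14, named after its values were seen, stayed at 0.189 ± 0.101 TPM in Primary and 0.184 ± 0.0980 TPM in Residual.

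Genes tied to the drugs and the disease were read out whatever their value. BCL2, the target of venetoclax, rose from 74.8 ± 8.00 TPM in Primary to 97.0 ± 6.81 TPM in Residual (adjusted p = 0.000962) and stood at 104 ± 9.73 TPM in Relapsed (adjusted p = 9.92e-05 against Primary). MCL1, another anti-apoptotic relative and also a member of the immediate-early list above, rose from 251 ± 24.3 to 445 ± 71.1 TPM in Residual (adjusted p = 9.90e-07) and was at 209 ± 10.7 TPM in Relapsed, 0.26 log2 below Primary (adjusted p = 0.0219). The MCL1 Relapsed versus Primary call ended without Primary replicate 3 (adjusted p = 0.0547) or Relapsed replicate 5 (adjusted p = 0.0549). BCL2L1 passed in no comparison (20.8 to 22.7 TPM on average). The BCL2 family as a list had 4 of 13 risen and 5 fallen in Residual by both adjustments (adjusted p = 0.938). UCK2, a kinase that activates azacitidine, was 0.31 log2 higher in Relapsed than in Primary (adjusted p = 0.000193) and 0.25 higher than in Residual (adjusted p = 0.000909). The UCK2 Relapsed versus Residual call ended under median-ratio scaling (adjusted p = 0.325), and the UCK2 Relapsed versus Primary call after the correction for gene length and GC content (adjusted p = 0.0516). Relative to the median of all genes, UCK2 in Relapsed was 0.07 log2 higher than in Residual and 0.14 higher than in Primary. The surface marker CLEC4C, also called BDCA-2, fell from 19.9 ± 2.70 to 10.7 ± 2.74 TPM in Residual and was at 20.9 ± 5.54 TPM in Relapsed. DNMT1, TET2 and the dendritic cell factor TCF4 did not pass, with adjusted p from 0.0532 to 0.954. TCF4 Relapsed versus Primary passed without Primary replicate 3 (0.29 log2, adjusted p = 0.00277), Residual replicate 1 (adjusted p = 0.0462) or Relapsed replicate 1 (adjusted p = 0.0300). TET2 Residual versus Primary passed without Primary replicate 3 (0.34 log2, adjusted p = 0.0312) and under median-ratio scaling (adjusted p = 0.0407), and TET2 Relapsed versus Residual passed under median-ratio scaling (-0.31 log2, adjusted p = 0.00872). DNMT1 Residual versus Primary passed without Primary replicate 5 (-0.27 log2, adjusted p = 0.0258). DNMT1 Relapsed versus Residual passed without Primary replicate 5, Relapsed replicate 2 or Relapsed replicate 3 (adjusted p = 0.0439, 0.0230 and 0.0385). DNMT1 Relapsed versus Primary turned to -0.20 log2 after the correction for gene length and GC content (adjusted p = 0.0115). Without that correction it was at -0.16 relative to the median of all genes. IL3RA, the interleukin 3 receptor that BPDCN carries, was listed at 0 in every library, as was SLC25A6, an ADP/ATP carrier that cells in general express, so its level cannot be read from the table.

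Over all genes, 1735 were higher and 1883 lower in Residual than in Primary, and 8578 did not pass. In 2424 genes (19.9%) the 5 libraries of one group all lay beyond the 5 of the other, where chance gives 0.794%. The lists for the title's subject were not called: of 7 measured genes of vitamin C transport and TET dioxygenases none rose and 2 fell by both adjustments (adjusted p = 0.435). Of 15 AU-rich element RNA-binding proteins 2 rose and 1 fell (1 and 0 adjusted over the list alone; adjusted p = 0.366). The other lists that were not called in Residual versus Primary were those of azacitidine metabolism and DNA methyltransferases (adjusted p = 0.445), the leukaemia stem cell score (7 genes measured; 0.147), cell cycle arrest and quiescence (0.128), p53 targets (0.974), endoplasmic reticulum chaperones (0.509), heat shock proteins (0.187), NRF2 and antioxidant genes (0.147), OXPHOS subunits (0.0667), glycolysis (0.147), hypoxia response (0.187), MYC targets (0.166), and adhesion and homing (0.249). The p-values measure only the spread between these libraries, since the labels do not say whether replicates came from separate mice.

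**Figure D4:**
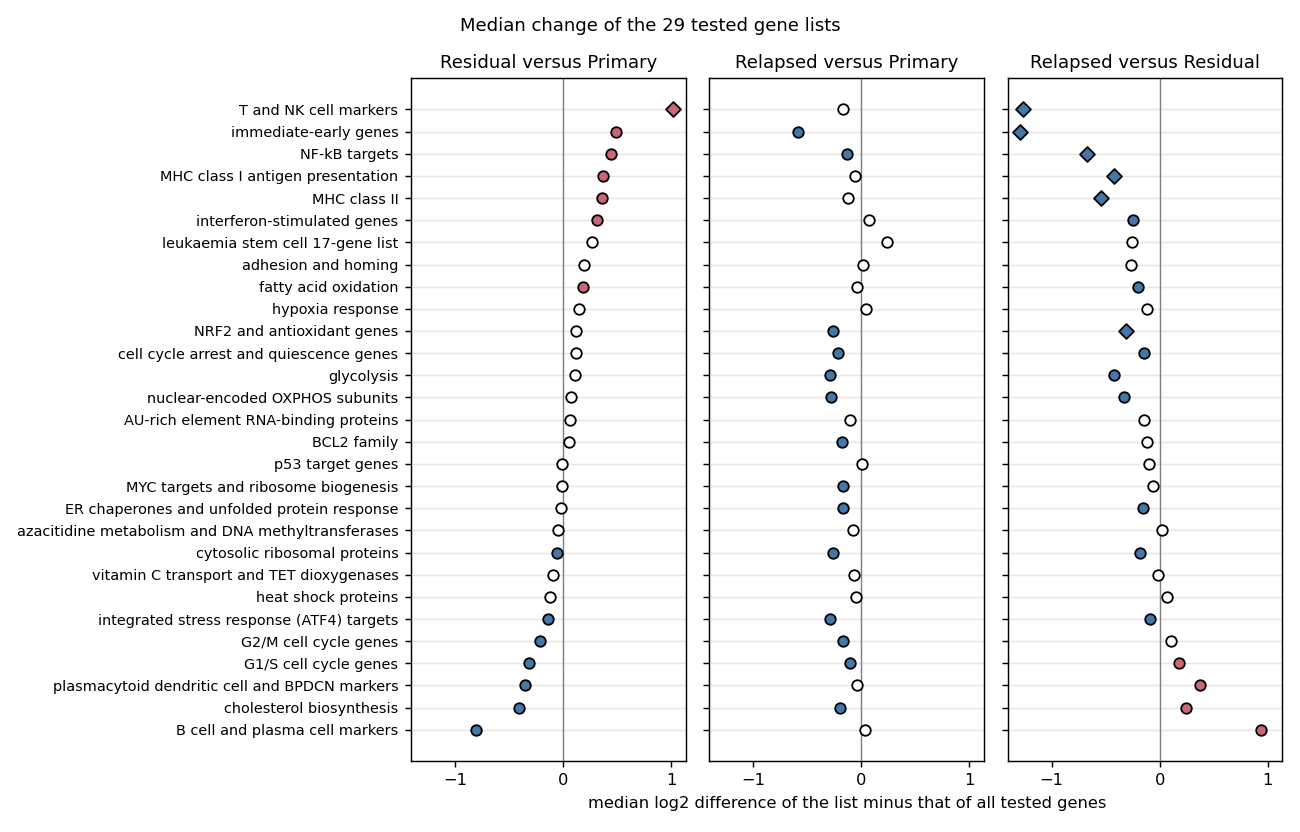
Median log2 difference of each of the 29 tested gene lists minus the median of all tested genes, by comparison; red and blue symbols are lists called higher and lower at an adjusted p of 0.05 with a preset correlation, open symbols are lists not called, and diamonds also passed with an estimated correlation. The T and NK cell list (1.02) and the B and plasma cell list (-0.81) were the extremes in Residual versus Primary; in Relapsed versus Primary the sign of the cytosolic ribosomal protein median turned under quantile normalization.

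The 8 largest falls in Relapsed cells, compared with Primary cells, included transcription factors and signalling genes. Of the genes below, NR4A3 and ATF3 are also members of the immediate-early list. The nuclear receptor NR4A3 was at 19.1 ± 5.40 TPM in Primary and 0.744 ± 0.115 TPM in Relapsed (adjusted p = 4.24e-11). The phosphodiesterase PDE4B went from 38.0 ± 6.25 to 7.24 ± 1.51 TPM, the AP-1 subunit FOSL2 from 24.0 ± 4.59 to 4.29 ± 0.571 TPM, and ATF3, a stress-induced transcription factor, from 77.1 ± 6.71 to 21.9 ± 2.84 TPM. STK17B, NINJ1, RASGEF1B and the insulin receptor substrate IRS2 completed the 8 largest falls, with log2 differences of -2.43, -2.14, -1.64 and -1.56. The largest rise was in CD180, a toll-like receptor relative, from 29.8 ± 2.77 to 91.1 ± 8.44 TPM, and the chemokine receptor CCR2 rose from 34.8 ± 3.50 to 80.7 ± 6.30 TPM. DUSP7, GIPR, FAM200A, TNFAIP8L2, HIST1H3E and KIF1BP rose by 1.17 to 1.28 log2.

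The median of all tested genes was 0.17 log2 higher in Relapsed than in each other group, and values called relative below are given minus that shift. Counts, TPM and adjusted p-values are as tested. Relative to it, CD180 was 1.41 and CCR2 1.02 log2 higher, NR4A3 was -3.66 and ATF3 -1.95. As tested, 5101 genes were higher and 728 lower in Relapsed than in Primary, so that 87.5% of the called genes were higher. Median-ratio scaling gave 2549 higher and 2662 lower, and quantile normalization 2294 and 2123. In 3380 genes (27.7%) the libraries of the 2 groups did not overlap, where chance gives 0.794%. Relative to the shift, 263 called genes were higher and 224 lower by at least 1.5-fold. No gene called here was called in the opposite direction under any of these scalings.

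Immediate-early genes were lower in Relapsed cells: 12 of 18 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -0.58 log2 relative to the shift. The immediate-early list had adjusted p = 1.22e-14, and adjusted p = 0.0866 with an estimated correlation. As these genes also respond to tissue dissociation, handling was not separated from the disease state. JUND went from 289 ± 15.3 to 160 ± 7.10 TPM. Of 21 targets of ATF4, 9 fell and 1 rose (9 and 2 adjusted over the list alone), with a relative median of -0.29. PPP1R15A, which reverses the translational block of the stress response, went from 461 ± 35.4 to 181 ± 17.9 TPM and DDIT3 from 93.8 ± 14.4 to 38.0 ± 1.48 TPM. The ATF4 target list had adjusted p = 5.46e-10, and adjusted p = 0.0866 with an estimated correlation. It shares ATF3 with the immediate-early list. NRF2 and antioxidant genes had 8 of 19 fallen and 2 risen by both adjustments, including FTH1, the ferritin heavy chain, at 1827 ± 41.0 against 1430 ± 85.1 TPM. NRF2 and antioxidant genes had adjusted p = 3.50e-05, and adjusted p = 0.0866 with an estimated correlation. Subunits of oxidative phosphorylation (OXPHOS) had 22 of 78 fallen and 4 risen (17 and 4 adjusted over the list alone) with a relative median of -0.28, and glycolysis genes 7 of 18 fallen and 2 risen (9 and 2 adjusted over the list alone) with -0.29. Examples were NDUFB11 of complex I (134 ± 7.79 to 111 ± 11.3 TPM) and PFKFB3, a regulator of glycolytic flux (42.1 ± 6.65 to 17.1 ± 1.83 TPM). Their list tests gave adjusted p = 1.11e-15 and 4.05e-06, and adjusted p = 0.329 for both with an estimated correlation. These 5 lists and cholesterol biosynthesis were also called under median-ratio scaling and quantile normalization. Cholesterol biosynthesis had 5 of 24 fallen and 5 risen by both adjustments, with a relative median of -0.20. That list had adjusted p = 0.00185, and adjusted p = 0.613 with an estimated correlation. The median change as tested followed abundance, from -0.10 log2 in the top 100 genes to 0.23 in genes at 1.00 to 24.2 TPM. It also rose with gene length, from 0.07 log2 in the shortest of 5 equal sets of genes to 0.21 in the longest. The lists were not compared with genes of like abundance, and their calls after the length and GC correction are not given here.

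A further 8 lists were called lower in Relapsed than in Primary, but each lost its call under at least 1 scaling, and none of the 14 lists kept its call with an estimated correlation. Cytosolic ribosomal proteins had 22 of 76 fallen and 2 risen (19 and 2 adjusted over the list alone; adjusted p = 2.40e-16), with a relative median of -0.26 that turned to 0.003 under quantile normalization (adjusted p = 0.727), and adjusted p = 0.49 with an estimated correlation. Endoplasmic reticulum chaperones, with HSPA5 at 467 ± 33.7 against 276 ± 21.7 TPM, had 9 of 21 fallen and 3 risen by both adjustments. The chaperone list had adjusted p = 0.000165, 0.299 under quantile normalization, and adjusted p = 0.49 with an estimated correlation. The BCL2 family had 5 of 13 fallen and 3 risen by both adjustments, including the pro-apoptotic PMAIP1, also called NOXA, at 178 ± 16.0 against 110 ± 14.9 TPM, and BAK1. The BCL2 family had adjusted p = 0.0125, 0.0572 under quantile normalization, and adjusted p = 0.0866 with an estimated correlation. Cell cycle arrest and quiescence genes had 6 of 19 fallen and 7 risen by both adjustments, with KLF6 among those that fell. The arrest list had adjusted p = 0.0125, 0.281 under quantile normalization, and adjusted p = 0.49 with an estimated correlation. MYC targets had 7 of 29 fallen and 10 risen (8 and 11 adjusted over the list alone), with NOP58, a ribosome assembly protein, among those that fell. The MYC list had adjusted p = 0.00327, 0.416 under quantile normalization, and adjusted p = 0.49 with an estimated correlation.

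The cell cycle and NF-kB lists were called lower only against the rise of all genes. G1/S genes had 5 of 40 risen and 3 fallen (2 and 0 adjusted over the list alone) with a median of 0.07 log2, which is -0.11 relative to the shift and turned to -0.09 under quantile normalization. G1/S genes had adjusted p = 0.0497, and adjusted p = 0.839 with an estimated correlation. G2/M genes had 7 of 50 risen and 2 fallen (5 and 1 adjusted over the list alone) with a median of 0.003 log2, which is -0.17 relative to the shift and turned to -0.14 under quantile normalization. G2/M genes had adjusted p = 0.000962, and adjusted p = 0.839 with an estimated correlation. NF-kB targets had 4 of 16 risen and 3 fallen (3 and 3 adjusted over the list alone), with a median of 0.04 and a mean of -0.05, and CD83 at 18.8 ± 2.39 against 7.34 ± 1.74 TPM. The median turned to -0.15 under median-ratio scaling, where the call ended. The NF-kB target list had adjusted p = 0.0172 as fitted and 0.0678 there, and adjusted p = 0.329 with an estimated correlation. The median, mean and test also differed in sign for endoplasmic reticulum chaperones (median 0.004, mean -0.05) and arrest genes (median -0.05, mean 0.008), and MYC targets (median -0.002, mean 0.03), all called lower.

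Markers of plasmacytoid dendritic cells were not called in Relapsed versus Primary (6 of 28 risen and 2 fallen, 5 and 1 adjusted over the list alone; adjusted p = 0.42), nor were the T and NK cell markers (1 of 9 risen and none fallen by both adjustments; adjusted p = 0.41) or the B and plasma cell markers (3 of 10 risen and none fallen by both adjustments; adjusted p = 0.664). The T and NK cell member that rose was GNLY, at 15.4 ± 4.42 against 36.3 ± 9.43 TPM. MHC class II (adjusted p = 0.552), MHC class I (0.657), interferon-stimulated genes (0.571), fatty acid oxidation (0.881), heat shock proteins (0.292), hypoxia response (0.700), p53 targets (0.0894), adhesion and homing (0.617), the leukaemia stem cell score (0.881), azacitidine metabolism and DNA methyltransferases (0.344), AU-rich element RNA-binding proteins (0.0986) and vitamin C transport (0.416) were not called.

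The 8 largest falls in Relapsed cells, compared with Residual cells, included several of the genes with the largest rises in Residual. AGR2 went from 93.7 ± 21.9 to 0.931 ± 0.430 TPM, GNLY from 527 ± 132 to 36.3 ± 9.43 TPM, LYZ from 21.4 ± 5.11 to 0.345 ± 0.0968 TPM and IL2RB from 21.2 ± 4.29 to 0.409 ± 0.120 TPM. The orphan nuclear receptors NR4A2 and NR4A3 went from 158 ± 21.3 to 11.3 ± 1.80 TPM and from 35.8 ± 6.05 to 0.744 ± 0.115 TPM; FAM46C and CD52 were the other members of the 8 largest falls, at -3.74 and -3.91 log2 relative to the shift. Among the 8 largest rises EPHA2 went from 0.590 ± 0.270 to 7.46 ± 4.04 TPM, PTCRA from 18.2 ± 5.07 to 67.6 ± 16.0 TPM, CHST15, a sulfotransferase, from 4.96 ± 1.43 to 23.9 ± 1.82 TPM, and the kinase NUAK2 from 8.13 ± 0.544 to 35.1 ± 4.45 TPM. KDELR3, SERTAD4, CD180 and VPREB3 were 1.64, 1.60, 1.58 and 1.45 log2 higher relative to the shift. In total 5539 genes were higher and 1380 lower (80.1% higher; 3285 and 3288 under median-ratio scaling, 3280 and 2932 under quantile normalization), 599 and 543 of them by at least 1.5-fold relative to the shift, and in 5241 genes (43.0%, against 0.794% by chance) the groups did not overlap.

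Of the 18 lists called in Relapsed versus Residual, 6 kept their call with an estimated correlation, and all 6 were lower in Relapsed under each scaling. Immediate-early genes had 15 of 18 fallen and 2 risen by both adjustments, with a relative median of -1.29. These immediate-early genes had adjusted p = 6.92e-19, and adjusted p = 0.0281 with an estimated correlation. Handling was not separated from the disease state here either. T and NK cell markers had 7 of 9 fallen and none risen by both adjustments (adjusted p = 1.67e-09; adjusted p = 0.00384 with an estimated correlation). NF-kB targets had 9 of 16 fallen and 5 risen by both adjustments, with TNFAIP3 at 77.4 ± 12.8 against 20.9 ± 2.65 TPM. NF-kB targets had adjusted p = 1.47e-05, and adjusted p = 0.0281 with an estimated correlation. MHC class II genes had 9 of 13 fallen and 1 risen (10 and 1 adjusted over the list alone), HLA-DRB1 returning to 92.6 ± 1.75 TPM (adjusted p = 3.49e-10; adjusted p = 0.0485 with an estimated correlation), and MHC class I genes 8 of 14 fallen and 1 risen by both adjustments. The class I list had adjusted p = 2.51e-05, and adjusted p = 0.0281 with an estimated correlation. NRF2 and antioxidant genes had 7 of 19 fallen and 2 risen by both adjustments, with FTH1 at 2285 ± 79.7 against 1430 ± 85.1 TPM. The NRF2 list had adjusted p = 2.51e-05, and adjusted p = 0.0281 with an estimated correlation.

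The 4 lists called higher in Relapsed than in Residual lost their calls with an estimated correlation. Plasmacytoid dendritic cell markers had 21 of 28 risen and 1 fallen by both adjustments, with MZB1 at 390 ± 53.8 against 843 ± 62.8 TPM, the nucleic acid sensor TLR7 at 19.9 ± 2.73 against 56.3 ± 6.58 TPM and the transcription factor SPIB at 241 ± 24.9 against 443 ± 31.2 TPM. This marker list had adjusted p = 0.000670, and adjusted p = 0.385 with an estimated correlation. G1/S genes had 35 of 40 risen and none fallen by both adjustments, 18 risen under median-ratio scaling, with CCNE2, cyclin E2, at 8.78 ± 1.74 against 20.5 ± 1.87 TPM and the replication licensing regulator DTL at 19.6 ± 2.98 against 35.7 ± 4.13 TPM. The G1/S list had adjusted p = 0.000238, and adjusted p = 0.544 with an estimated correlation. Cholesterol biosynthesis had 20 of 24 risen and none fallen by both adjustments, with SQLE at 5.47 ± 1.23 against 17.8 ± 3.25 TPM. The cholesterol list had adjusted p = 0.00448, and adjusted p = 0.511 with an estimated correlation. B and plasma cell markers had 8 of 10 risen and 1 fallen by both adjustments, with CD79A at 12.1 ± 0.626 against 34.7 ± 5.32 TPM and PAX5 at 1.15 ± 0.227 against 4.73 ± 0.847 TPM. The B cell list had adjusted p = 0.0211, and adjusted p = 0.385 with an estimated correlation. Of all 12196 tested genes 5539 rose in this comparison as tested, so part of the risen members goes with the general shift. The relative medians of these 4 lists were 0.37, 0.17, 0.25 and 0.94.

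The remaining 8 lists were called lower in Relapsed than in Residual. OXPHOS subunits had 42 of 78 fallen and 3 risen by both adjustments, including ATP5L and COX4I1, with a relative median of -0.33 (adjusted p = 3.27e-14; adjusted p = 0.284 with an estimated correlation), and glycolysis genes 12 of 18 fallen and 4 risen by both adjustments, including TPI1 and LDHA, with -0.42. The glycolysis list had adjusted p = 1.44e-05, and adjusted p = 0.302 with an estimated correlation. Fatty acid oxidation genes had 6 of 18 fallen and 3 risen by both adjustments, with CPT1A, which fell by 1.28 log2 relative to the shift from 109 ± 11.9 TPM. The fatty acid list had adjusted p = 0.00935, 0.0799 under quantile normalization, and adjusted p = 0.302 with an estimated correlation. Cell cycle arrest and quiescence genes had 8 of 19 fallen and 7 risen by both adjustments. The quiescence list had adjusted p = 0.00935, 0.0851 under median-ratio scaling, and adjusted p = 0.385 with an estimated correlation. Their median was 0.03 log2, their mean -0.24 and their median under median-ratio scaling -0.16. Those that fell included KLF4 (58.9 ± 6.11 to 10.9 ± 1.80 TPM), KLF2 (11.4 ± 1.53 to 1.54 ± 0.306 TPM) and TOB1 (132 ± 16.8 to 45.6 ± 2.56 TPM). ATF4 targets (adjusted p = 0.0479; 0.122 under quantile normalization), endoplasmic reticulum chaperones (0.0178; 0.566 under quantile normalization), cytosolic ribosomal proteins (0.000106; 0.547 under quantile normalization, where the relative median turned to 0.02) and interferon-stimulated genes (0.0445; 0.408 under median-ratio scaling) each lost their call under a scaling. With an estimated correlation these 4 had adjusted p = 0.511, 0.538, 0.610 and 0.410.

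Their counts were 4 of 21 ATF4 targets fallen and 5 risen, 6 of 21 chaperones fallen and 4 risen, 9 of 76 ribosomal protein genes fallen and 2 risen (5 and 1 adjusted over the list alone), and 10 of 29 interferon-stimulated genes fallen and 13 risen; except for the ribosomal proteins the counts adjusted over the list alone were the same. The medians of the first pair as fitted were 0.08 and 0.02 log2 and turned to -0.11 and -0.18 under median-ratio scaling. Lists not called in this comparison were G2/M genes (24 of 50 risen and none fallen by both adjustments; adjusted p = 0.397), the BCL2 family (0.0979), p53 targets (0.0979), heat shock proteins (0.857), hypoxia response (0.422), MYC targets (0.373), adhesion and homing (0.170), the leukaemia stem cell score (0.112), azacitidine metabolism and DNA methyltransferases (0.863), AU-rich element RNA-binding proteins (0.0794) and vitamin C transport (0.857).

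Genes that changed in Residual were followed into Relapsed. Of the 1735 genes higher in Residual than in Primary, 883 (50.9%) were lower in Relapsed than in Residual and 885 were still higher in Relapsed than in Primary, among them GNLY. Of the 1883 genes lower in Residual, 1569 (83.3%) were higher again in Relapsed, among them SLC23A1 and MZB1, and 261 were still lower than in Primary. Which share was larger, and which direction more genes kept, depended on the scaling: under median-ratio scaling 67.9% of the higher and 61.7% of the lower genes changed back, under quantile normalization 69.6% and 63.5%, and after the correction for gene length and GC content 70.5% and 63.5%. Under these 3 settings 599, 513 and 645 genes were still higher than in Primary and 711, 686 and 935 still lower. All 3 settings centre the libraries. As tested, changing back was not always a return to the Primary level. Of the 883 genes, 215 were still higher than in Primary, 572 had no call against Primary and 96 were lower. Of the 1569 genes, 60 were still lower than in Primary, 953 had no call against Primary and 556 were higher. Together 2452 genes changed back and 157 changed further in the same direction. Independent lists of these sizes would share 196 genes that rose then fell and 855 that fell then rose. These numbers do not allow for the Residual libraries that both comparisons use. Simulated libraries in which no gene differed shared none. Hardly any gene is called in such libraries, so that outcome was fixed in advance and is no measure of the overlap. Across genes, which are not independent replicates, r between these 2 sets of changes was -0.754 against -0.501 in the simulation, with a covariance of -0.116 against -0.00526, and -0.732 to -0.667 when the Residual libraries were split between the comparisons. Changes of Residual and of Relapsed against Primary correlated at r = 0.163, where shared Primary libraries alone gave 0.503 in the simulation. The covariances were 0.0166 and 0.00529, and r was 0.0166 to 0.147 with the Primary libraries split. The 2 comparisons shared 885 genes higher and 261 lower, against 726 and 112 for independent lists. The simulation gave 0 and 0, which was fixed in advance in the same way. Under the 3 other settings more of the shared genes were lower than higher. As tested, 652 genes called in both went in opposite directions.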

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

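This check was fixed before the results were seen, and no test of the values below was chosen after them.

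A library stood out where its gap to the nearest of the other 4 in its group was more than 0.71 of the range of the 5 values. By chance about 1 in 20 groups of values has such a library; 329 groups were examined and 15 had one. No cause was tested.

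In Relapsed replicate 2, EPHA2 was at 14.6 TPM (others 4.93 to 6.63), PTCRA at 96.0 (57.5 to 63.2) and HLA-DQA1 at 168 (157 to 159), and LDHA was lowest at 319 (346 to 355). In Relapsed replicate 3, SQLE was lowest at 12.3 TPM (18.4 to 20.7). The share of mitochondrial ribosomal RNA in Relapsed replicate 4 was 2.95% (others 2.65% to 2.73%).

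In Residual replicate 2, NR4A2 was at 195 TPM (others 142 to 156), RASGEF1B at 41.9 (36.6 to 37.6) and NINJ1 at 15.6 (11.7 to 12.6). In Residual replicate 4, PPP1R15A was lowest at 434 TPM (503 to 531) and SLC25A20 highest at 57.6 (51.3 to 52.5). In Residual replicate 1, HIST1H3E was at 9.70 TPM (4.54 to 5.95).

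In Primary replicate 3, STK17B was at 66.9 TPM (others 33.0 to 34.5). In Primary replicate 5, HIST1H2BB was lowest at 4.83 TPM (9.49 to 10.4) and GIPR at 4.93 (5.88 to 6.18).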

How the results depend on the processing

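A minimum fold of 1.5, the removal of rRNA, 7SL and ribosomal protein genes and the correction for gene length and GC content were added after the data were seen; the other settings were fixed beforehand. The cause of each difference was not tested.

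Counts depended on the scaling and on a minimum fold. Relapsed versus Primary had 2549 genes higher and 2662 lower under median-ratio scaling, 2294 and 2123 under quantile normalization and 2635 and 2995 after the length and GC correction, against 5101 and 728 as first tested. Relapsed versus Residual had 3285 and 3288, 3280 and 2932, and 3572 and 3411 in the same order, against 5539 and 1380. Each of these settings centres the libraries, which by itself brings the counts near even. The counts after the length and GC correction therefore do not show that length or GC content caused the imbalance. With a minimum fold of 1.5 the counts were 216 higher and 62 lower in Residual versus Primary, 35 and 35 in Relapsed versus Primary and 265 and 191 in Relapsed versus Residual, and 176 genes changed back. The correlation of changes was 0.218 with a pseudocount of 0.1, against 0.163. Called lists in Relapsed versus Primary numbered 7 under quantile normalization, and 1, 0 and 6 lists were called with an estimated correlation in the 3 comparisons.

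SLC23A1 Relapsed versus Primary passed with sample weights (0.25 log2, adjusted p = 0.0380). SLC23A1 Residual versus Primary, at -0.87 log2, was not shown to exceed a fold of 1.5 by the test with that minimum (adjusted p = 0.57). KHSRP Relapsed versus Residual reversed under median-ratio scaling (-0.14, adjusted p = 0.0302) and after the length and GC correction (-0.13, adjusted p = 0.0150), as did KHSRP Relapsed versus Primary after that correction (-0.13, adjusted p = 0.0189) and DNMT1 Relapsed versus Primary (-0.20, adjusted p = 0.0115). As tested but relative to the median of all genes, KHSRP was at -0.12 log2 against Residual and -0.10 against Primary. On the same scale DNMT1 was at -0.16 against Primary.

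With replicate number as a block, 1620 genes were higher and 1701 lower in Residual versus Primary, 4824 and 671 in Relapsed versus Primary, and 5360 and 1310 in Relapsed versus Residual. Equal replicate numbers did not pair the libraries: of 15 pairs 3 had a correlation above 0.1, and in 0 was it the best match.

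Leaving out 1 library gave 1454 to 2011 genes higher and 1485 to 2307 lower in Residual versus Primary, 4368 to 5580 and 597 to 751 in Relapsed versus Primary, and 4903 to 5751 and 1214 to 1461 in Relapsed versus Residual. SLC23A1 ranged from -0.97 to -0.80, from 0.13 to 0.31 and from 1.04 to 1.18 log2. KHSRP ranged from -0.04 to 0.07, from 0.01 to 0.12 and from 0.02 to 0.08 log2. Called lists ranged from 13 to 15, 13 to 15 and 16 to 18. The correlation of changes was 0.143 to 0.197, and 2052 to 2821 genes changed back.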

Other observations

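Of the tests below, those of mouse RNA, of a library-wide difference, of S phase and of germline genes were chosen after the result was seen. Genes first named in this part were chosen after their values were seen.

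Replication-dependent histone genes, which are outside the fixed lists, were counted as a group and were not tested as a list. Of 55 measured, 32 fell and 2 rose in Residual versus Primary (median -0.88 log2), 25 fell and 4 rose in Relapsed versus Primary (median -0.58 relative to the median of all genes), and 25 rose and 2 fell in Relapsed versus Residual (relative median 0.25). Of all 12196 tested genes 5539 rose in that comparison, a count that depended on the scaling, so the 25 of 55 are about the general share. Separately, KIT, a stem cell factor receptor, went from 8.00 TPM in Primary to 48.4 ± 5.48 in Residual and 16.3 ± 1.78 in Relapsed. SAMHD1, a dNTP hydrolase, went from 92.4 ± 11.2 TPM in Primary to 202 ± 29.2 in Residual.

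Some genes nearly silent in Relapsed were measured in Residual. Among 6252 genes with a mean below 0.5 TPM in Relapsed, 589 were higher and 89 lower in Residual than in Primary, so that 86.9% of the called ones were higher. Of the 6252 genes, 6167 were below 0.5 TPM in Primary too, so that a called gene had little room to go down, and this share does not bear on whether silent genes were turned on. It met the bound of at least 75% written beforehand, and the reading was changed to open after the value was seen, as was that of the germline genes below. Those that reached a mean of at least 5 TPM in Residual included LYZ, IL2RB, CD247, LINGO4 (5.86 ± 0.602 TPM) and OSR2 (5.75 ± 0.527 TPM), and admixed cells were not separated from a change within the cells. Of 29 germline and cancer-testis genes 6.90% were called higher. As 17 were listed at 0 in every library, which cannot be read as absence here, release of germline genes by demethylation stays open.

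The rise of T and NK cell markers in Residual could reflect admixed human NK cells or RNA from the mouse. Over 14 other genes abundant in NK cells the median gain was 0.00672% of the gain of GNLY (0.0627% over the 11 not listed at 0 in every library). This argues against NK cells in proportion to GNLY. However, 6 of the 14 were called higher and 0 lower. They were CTSW (8.75 to 52.8 TPM), CST7 (0.170 to 3.35 TPM) and, below the filter, KLRB1 (0.0326 to 1.55 TPM), CD160 (0.0626 to 1.16 TPM), KLRC1 (0.00382 to 0.601 TPM) and NCR1 (0.000961 to 0.0530 TPM). A smaller admixture of NK cells stays open. GNLY made up 84.2% of the TPM gained by the list, and mice lack granulysin, which argues against mouse RNA as the source of most of that TPM. This share does not bear on the other members that rose, such as NKG7 and CD247. An effect of the treatment or the disease state was not tested and remains open.

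Most called genes were higher in Relapsed than in Primary, which could come from a few abundant genes, from gene length or GC content, from depth or from a library-wide difference. Without the 100 most abundant genes 80.2% of called genes were still higher, which argues against those genes alone, and among libraries with a relative depth of at most 2 the share was 85.0%, which argues against depth. The share higher followed abundance, however, at 7.89%, 42.6%, 85.3% and 93.8% from the most to the least abundant of 4 sets of genes, so a shift spread over many abundant genes stays open. The share also rose with gene length, at 69.1%, 84.3%, 91.0%, 92.8% and 95.6% from the shortest to the longest of 5 equal sets. By GC content it was 85.1% to 92.6%. The lowest share, 69.1%, lay between the bounds of 60% and 75% set beforehand, so gene length or GC content stays open as a source. After median-ratio scaling the share was 48.9%, but centring fixes that outcome and cannot separate the state from a library-wide difference or a change in total RNA per cell. The correction for gene length and GC content centres the libraries too, so its share of 46.8% does not bear on length or GC content.

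The lower histone genes in Relapsed than in Primary could come from poorer capture of RNAs without a poly(A) tail or from fewer cells in S phase. Tested RNAs without such a tail had a median of 0.0639 log2 relative to all genes. This met the bound written beforehand for ruling capture out, a median above -0.1; after the value was seen the label was changed to open, because only 5 of the 20 such RNAs were in the table and they went both ways. The G1/S list had a relative median of -0.105 (-0.150 to -0.0570 without a library), short of the -0.2 set for S phase, which leaves it open. That test replaced another one after its value was seen, because the other assumed that histone and G1/S genes change in proportion.

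Of 100 splits of the libraries only 1, the real grouping, gave as many called genes in each comparison. This argues against chance only if the libraries are independent, and the labels do not say whether replicates came from separate mice. The real counts were 3618, 5829 and 6919 and the highest counts of the other splits were 1066, 3922 and 1854.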
